A study of Mus musculus with 2 samples.

How the data were processed

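The deposited matrices hold UMI counts per gene and droplet barcode, as the authors' Cell Ranger run called them, with 1 matrix per library and 32286 features in each. Per the submitters' processing notes, reads were aligned with Cell Ranger 5.0.1 to the mouse genome mm10, and the file headers show an eYFP feature added to the mouse genes. All values in both matrices were whole numbers, and the lowest total of a listed barcode was 500 UMIs in both libraries. Genes were matched by gene identifier to GENCODE release M21 (GRCm38), which held 32158 of the features and lacked 128, eYFP among them. For 2 list members the files carry a newer symbol, Ccn2 for Ctgf and Ccn3 for Nov. The files were read as raw counts, so nothing had to be undone before they were summed or scaled.

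Per the labels' protocols, dorsolateral flank skin of littermates at embryonic day E13.5 was dissected, and after genotyping 2 to 3 embryos were pooled per group. The skin was dissociated in 0.25% trypsin for 20 minutes at 37 °C, and live cells were sorted by exclusion of DAPI. Libraries were made with 10x Genomics 3′ chemistry in parallel and sequenced on the same lane of an Illumina NovaSeq. The genotype field of each library contradicts its title: the library titled control carries the entry for the mutant genotype, and the library titled mutant carries the entry for the wild type. Groups follow the titles. The choices below on groups, classes, lists, named genes and settings were made before the data were examined, except where the text says that a value was chosen later.

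Barcodes with fewer than 1000 detected genes or more than 10% mitochondrial UMIs were left out, which kept 12120 barcodes of the control library and 8783 of the mutant library. Scrublet, run per library in scanpy 1.11.5 with an expected doublet rate of 8%, called 594 doublets (4.90%) in the control library and 277 (3.15%) in the mutant library at score thresholds of 0.2815 and 0.307. Without them 11526 and 8506 cells were kept, with a median of 7440.5 UMIs and 2544 genes per cell in the control library and 6660 UMIs and 2315 genes in the mutant library. Barcodes under 1000 genes numbered 1413 and 3087, of which 376 and 2448 had at least 50% of their UMIs from hemoglobin genes. The software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.

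Counts of kept cells were scaled to 10000 per cell and log transformed, 2000 variable genes and 30 principal components were taken, and cells of both libraries were clustered together by the Leiden algorithm at resolution 1.0 on 15 neighbours, with no batch correction. Clusters were named from 14 fixed marker lists. A cluster took the class whose markers had the highest mean log ratio to the average of all classes, where at least 3 of these markers reached 10 CPM, where the 10 leading genes held no more markers of any other class, and where these held at least 1 marker of the class or most of its list was detected. The last condition was relaxed to this form after the clusters were seen. Class names are therefore marker calls, written with the suffix "-like" at first use and without it after that. The dermal class took clusters 1, 2, 3, 4, 5, 6, 8, 10, 12, 13, 14, 16 and 24, and the epidermal class took clusters 9, 11 and 28.

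For each class and library the UMIs of all cells were summed and scaled to a total of 1000000, as CPM. With 1 library per group there was no test between groups and no p-value. A ratio of CPM values carries an exact conditional binomial 95% interval, a CPM an exact Poisson interval and a share an exact Clopper-Pearson interval, and all of them cover counting error only. Beside a count of 0 cells or 0 UMIs of a gene, the text gives the share or CPM that 3 counts would make. A difference between shares carries an interval built from those of the 2 shares. UMIs of 1 cell are not independent draws from the embryos, so such intervals are narrower than the spread between animals, which these files cannot show. Differences between class totals were small for the typical gene: the median log2 ratio was 0.01 in dermal cells and 0.06 in epidermal cells, and a trimmed mean of M values (TMM) computed for the purpose gave log2 factors of 0.00 and 0.05.

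Each of 26 gene lists was summarised as the median log2 ratio, mutant over control, of members with at least 10 CPM in either library, with 1 CPM added to both values. Its interval comes from 1000 redraws of the counts, and its percentile from 10000 random lists of the same size matched on mean expression, which describes these libraries and is not a test. Members at a ratio of at least 1.5 either way are counted as higher or lower, and the others as within 1.5-fold. Genes were named by a fixed rule. Among genes with at least 20 CPM in either library, ranked by log2 ratio with 5 CPM added, it took the 12 highest and 12 lowest in dermal cells, 6 and 6 in epidermal cells, and 3 and 3 in other classes with at least 200 cells per library, where the interval of the ratio excluded 1. Mitochondrial, ribosomal protein and hemoglobin genes, Xist, Tsix, Ddx3y, Eif2s3y, Kdm5d and Uty, and clone names were left out, and Gli1, Ptch1, Hhip, Smo, Axin2, Lef1, Sox2, Sox18, Foxd1, Tbx18 and Cdkn1a were always included, along with up to 4 members of each list. Some genes taken by the rule are not reported here by name, although they stay in the list medians. The reporter eYFP fell among the 12 highest in dermal cells. Its values in other classes, Col1a1 and other genes named outside this rule were chosen after their values were seen.

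Per-cell shares were computed after each cell was thinned at random to 3000 UMIs, with shallower cells left out. A cell counted toward the condensate share with UMIs of at least 3 of the 12 genes Sox2, Sox18, Foxd1, Tbx18, Cdkn1a, Bmp3, Gal, Cxcr4, Hey1, Ntrk3, Prdm1 and Inhba, and toward the cycling share with at least 3 UMIs summed over the 8 genes Mki67, Top2a, Cdk1, Ccnb1, Ube2c, Birc5, Cenpf and Nusap1. Alternatives covered the gene minimum, the mitochondrial limit, doublets kept, clustering resolution, scaling, thinning, pseudocount, expression floor, cells without UMIs of the G2M genes and the per-cell minimum. Alternatives chosen after seeing the data were class totals without hemoglobin, cells with a Lef1 UMI, cells without UMIs of immediate early genes, and erythroid cells counted as dermal.

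The calculation was tried on simulated counts with a known answer, drawn for each library from the mean expression of a class at the class's real depths, with chosen genes scaled up or down. Among 5438 unchanged dermal genes, 95.02% of intervals held the true ratio of 1. Of 50 genes each at 1.5, 2, 4 and 8-fold, intervals held the truth for 94%, 92%, 88% and 96%, and every gene was placed on the correct side. In epidermal cells 95.28% of 4749 intervals held the truth for unchanged genes, and 96%, 94%, 96% and 94% for genes changed at those folds. Lists of 12 genes raised 2-fold reached percentile 100 in both classes, and lists of 12 unchanged genes stood at percentiles 4.43 and 78.7. The simulated counts held Poisson counting error alone, so they check the calculation and not the spread between cells or embryos.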

Results

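Gene expression was measured in single cells of embryonic mouse skin at stage E13.5, shortly before hair placodes become visible in the back skin. The mutant combined Axin2CreER, a tamoxifen-inducible recombinase in cells that respond to Wnt, with a SmoM2YFP allele at the Rosa locus, which after recombination yields a constitutively active Smoothened fused to a yellow fluorescent protein and so switches Hedgehog signalling on. The comparison asks what Hedgehog activation in Wnt-responding cells does to the dermis and its neighbours before hair follicles form. Each group had 1 library made from 2 to 3 pooled embryos, so no difference reported here has a replicate check, and intervals cover counting error only. The control library held 13566 barcodes with 109629368 UMIs in total and a median of 7217 UMIs and 2478 genes per barcode. The mutant library held 11909 barcodes with 73809828 UMIs, a median of 5577 UMIs and 2055 genes. After filtering, 11526 control and 8506 mutant cells remained, with 96669836 and 60661038 UMIs. The titles of the libraries and their genotype fields name opposite groups, and "control" and "mutant" below mean the libraries so titled. The title of the control library names the SmoM2YFP allele alone, without the recombinase.

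Dermal mesenchymal-like cells (dermal cells below) of the mutant library carried high levels of the direct Hedgehog targets and of the reporter. Ptch1, which encodes the Hedgehog receptor, was higher 45.5-fold (interval 40.8 to 50.8), at 247 CPM against 5.42. Gli1, a transcriptional effector of the pathway, was higher 11.6-fold (9.94 to 13.6), with 1127 UMIs against 190. Hhip, a secreted Hedgehog antagonist, was higher 33.6-fold. The eYFP transcript had 927 UMIs in mutant and 26 in control dermal cells, a ratio of 69.7 (47.3 to 107), so reporter and targets both go with the titles and against the genotype fields. UMIs assigned to the Smo gene differed by 1.19-fold (1.13 to 1.26). Whether the SmoM2YFP transcript counts toward Smo in these 3′ libraries was not tested. The dermal sums rest on 8712 control cells with 62919789 UMIs, mostly from clusters 1, 3, 4, 6, 8, 10 and 12, and on 5130 mutant cells with 32167951 UMIs, mostly from clusters 2, 5, 1 and 16. Because the libraries occupied largely separate dermal clusters, no comparison was made within them.

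In GRCm38 coordinates (GENCODE M21), Ptch1 (ENSMUSG00000021466) lies on chromosome 13 at 63508328 to 63573598 on the minus strand, and Gli1 (ENSMUSG00000025407) on chromosome 10 at 127329882 to 127341974 on the minus strand. Foxd1 (ENSMUSG00000078302) is on chromosome 13 at 98354242 to 98359305, Cdkn1a (ENSMUSG00000023067) on chromosome 17 at 29090976 to 29100727, Lef1 (ENSMUSG00000027985) on chromosome 3 at 131110471 to 131224356 and Dkk4 (ENSMUSG00000031535) on chromosome 8 at 22624043 to 22627547, all on the plus strand. All are protein-coding genes.

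As a group, the 4 core Hedgehog targets had a median log2 ratio of 4.68 (4.56 to 4.81) in dermal cells, above all of the 10000 matched random lists. With 10 CPM added before the ratio, the median was 2.80. Of 7 measured wider Hedgehog targets, 4 were higher and 3 within 1.5-fold, with a median of 0.62 (0.59 to 0.64). The higher members were Prdm1 (3.57-fold), the cell cycle gene Ccnd1 (2.03-fold), the growth factor gene Igf1 (1.82-fold) and Ccnd2 (1.53-fold). Among 8 receptors and transducers of the pathway none was higher, 2 were lower and 6 were within 1.5-fold, at a median of -0.21 (-0.29 to -0.15). The lower members were Gli3, which acts largely as a repressor, 1.61-fold lower, and Disp1, 1.52-fold lower.

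**Figure D1:**
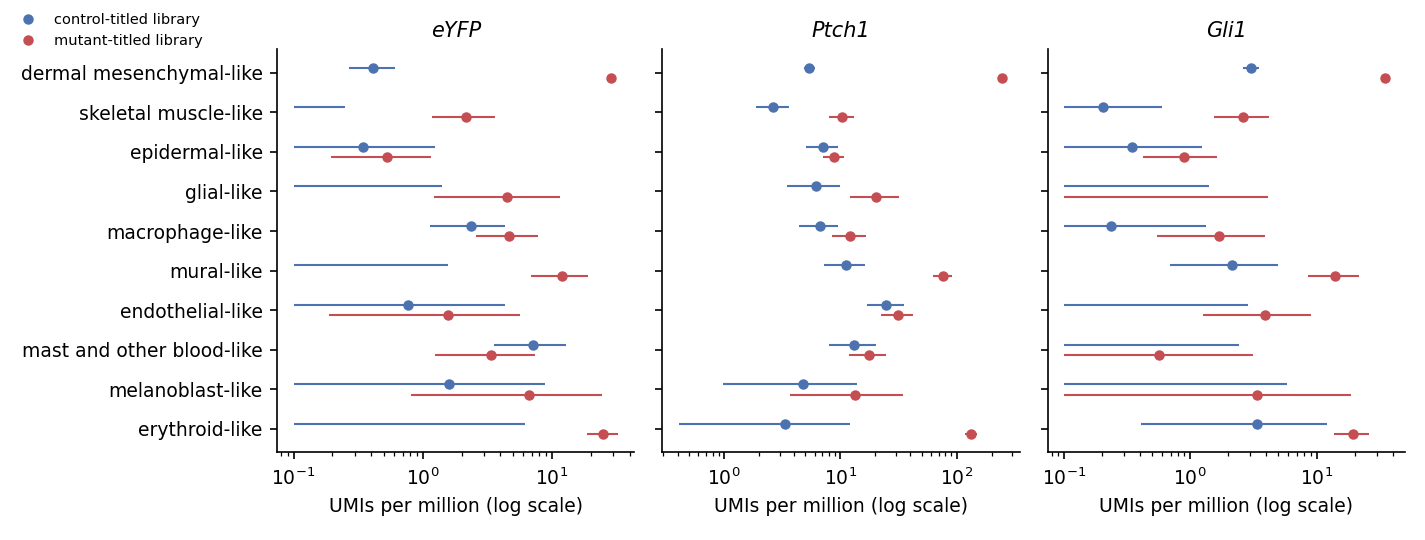
CPM (log scale) of eYFP, Ptch1 and Gli1 in the summed cells of each class, with points for each library and lines for exact 95% Poisson intervals, a line without a point standing for 0 UMIs. In dermal cells Ptch1 stood at 5.42 in the control library and 247 in the mutant library.

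Among the classes of the mutant library, Ptch1 was highest in dermal cells, followed by erythroid-like and mural-like cells. The erythroid-like cells held 284 Ptch1 UMIs (134 CPM) and 53 eYFP UMIs in 225 cells. Outside hemoglobin they also held the collagen gene Col1a1 at 589 CPM, beside 988 CPM in mutant dermal cells. Their Ptch1 and eYFP were therefore not separated from dermal RNA in the same droplets. In dermal cells 56.4% had a Ptch1 UMI in the mutant library and 3.66% in the control library, at median depths of 5865 and 6881.5 UMIs. For Gli1 the shares were 17.9% and 2.03%, and for eYFP 15.8% (810 cells) and 0.298%. Epidermal-like cells, taken as background for the reporter, had an eYFP UMI in 0.429% of mutant and 0.360% of control cells at medians of 7675 and 9783.5 UMIs, and the control dermal share was no higher than these. The share was not uniform across classes: macrophage-like cells had an eYFP UMI in 3.32% of mutant and 2.84% of control cells, and mast and other blood-like cells in 2.35% of mutant and 7.96% of control cells (9 cells), at medians of 8672, 11125.5, 10119.5 and 12547 UMIs. The epidermal Gli1 shares were 0.716% in the mutant and 0.360% in the control library, and the epidermal Ptch1 shares 4.87% and 7.01%. Mural-like cells, which surround blood vessels, had 17 eYFP UMIs in the mutant library and 0 in the control library, which allows up to 1.28 CPM at 3 counts, with Ptch1 at 75.9 against 11.1 CPM and Gli1 at 14.1 against 2.13 CPM. Within the mutant dermis, cells with an eYFP UMI had Ptch1 at 307 CPM and cells without one had 232 CPM. Hhip was at 209 CPM in the former and 130 CPM in the latter.

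Genes of the dermal condensate, the cluster of dermal cells that forms beneath a hair placode and later becomes the dermal papilla, were high in the mutant dermis. Foxd1, a forkhead transcription factor of condensate cells, was at 79.5 against 0.445 CPM, 179-fold higher (123 to 269). Gal, which encodes the neuropeptide galanin, was 130-fold higher (92.2 to 189), the transcription factor Sox18 37.2-fold (28.2 to 50.1) and the cell cycle inhibitor Cdkn1a 19.8-fold (18.1 to 21.7). Sox2, another condensate factor, was scarce in both libraries, with 157 UMIs against 4, a ratio of 76.8 (29.4 to 285). Tbx18, a T-box gene, was 3.01-fold higher (2.82 to 3.22).

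Of 12 measured condensate genes, 7 were higher, 3 lower and 2 within 1.5-fold, at a median log2 ratio of 1.57 (1.46 to 1.67), above all random lists. Trps1, a zinc finger transcription factor gene, was 19.3-fold higher. The lower members encode signals of the TGF-beta family: Inhba was 2.14-fold lower, Bmp4 1.84-fold lower and Tgfb2 at 15.9 against 31.8 CPM. Bmp7 and Rspo3 were within 1.5-fold. The median was 2.85 over the 6 members with at least 50 CPM, 2.68 in cells with a Lef1 UMI (chosen after seeing the data) and 1.01 with 10 CPM added.

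After thinning to 3000 UMIs, 497 of 4782 mutant dermal cells (10.4%, 9.54 to 11.3) had UMIs of at least 3 of the 12 condensate genes scored, against 13 of 8425 control cells (0.154%, 0.0822 to 0.264). The difference was 10.2 points (9.38 to 11.1), and 19.6 points with at least 2 genes. As background, 1 of 1375 mutant epidermal cells (0.0727%) met the condition. It was met by 0 of 550 control epidermal cells, which at a limit of 3 counts allows a share of up to 0.545%, by 0 of 977 control muscle cells, up to 0.307%, and by 0 of 696 mutant muscle cells, up to 0.431%. The upper ends of the exact intervals were 0.668%, 0.377% and 0.529%.

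Wnt targets went both ways in the dermis. The secreted Wnt inhibitor gene Dkk1 was 3.77-fold higher (3.61 to 3.93) at 187 against 49.7 CPM, the Wnt effector Lef1 2.32-fold (2.18 to 2.47) and the feedback inhibitor Axin2 1.76-fold (1.67 to 1.86). Of 15 measured targets these 3 were higher, 5 were lower and 7 were within 1.5-fold, with a median log2 ratio of -0.23 (-0.28 to -0.19), at percentile 0.13 of random lists. The lower members were the transcription factor Sp5 (3.29-fold lower), the Wnt deacylase Notum (3.14-fold lower), Tcf7 (2.69-fold lower), Twist1 (1.67-fold lower) and Apcdd1 (1.64-fold lower). The median depended on the cells taken. In cells with no UMI of the 8 G2M genes its direction was reversed, at 0.15. In cells with a Lef1 UMI it stayed negative, at -0.041 (chosen after seeing the data).

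Condensate genes were highest in mutant dermal cells with many Wnt target UMIs. For this view, chosen after the first values were seen, thinned dermal cells were placed in 4 ranges of the UMI sum of 17 Wnt targets, Dkk1 excluded: 0 to 2, 3 to 4, 5 to 7, and 8 to 23. The summed condensate genes stood at 257, 391, 668 and 1341 CPM over these ranges in the mutant library, and at 84.1, 93.8, 116 and 162 CPM in the control library. The core Hedgehog targets stood at 369, 425, 489 and 605 CPM in the mutant library and between 10.6 and 18.2 CPM in the control library. The reporter eYFP stood at 27.6, 27.5, 28.1 and 25.1 CPM in the mutant library. These are ranges of a score and not cell types, and 2703 of 8425 control and 1626 of 4782 mutant cells lay at a boundary. Dermal marker genes summed to medians of 27, 29, 29 and 28 UMIs per mutant cell and 39, 40, 39 and 38 per control cell over the ranges, and epidermal and muscle markers to a median of 0 in every range of both libraries.

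Single genes were also compared after mutant dermal cells were parted by a Lef1 UMI, 1045 cells with one and 4085 without. Foxd1 was at 221 CPM in cells with a Lef1 UMI and 42.8 CPM in the others, Gal at 249 and 20.9 CPM, Sox18 at 80.6 and 18.5 CPM, and Cdkn1a at 422 and 101 CPM. Ptch1 was at 408 and 205 CPM, while Hhip was at 126 and 150 CPM and the collagen gene Col1a1 at 481 and 1117 CPM. In the control dermis, parted alike into 1326 and 7386 cells, Gal was at 2.03 and 0.194 CPM, Sox18 at 1.59 and 0.679 CPM and Cdkn1a at 19.5 and 6.01 CPM. Foxd1 went the other way there, with 0 UMIs in cells with a Lef1 UMI, which allows up to 0.264 CPM at 3 counts, and 0.543 CPM in the others.

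**Figure D2:**
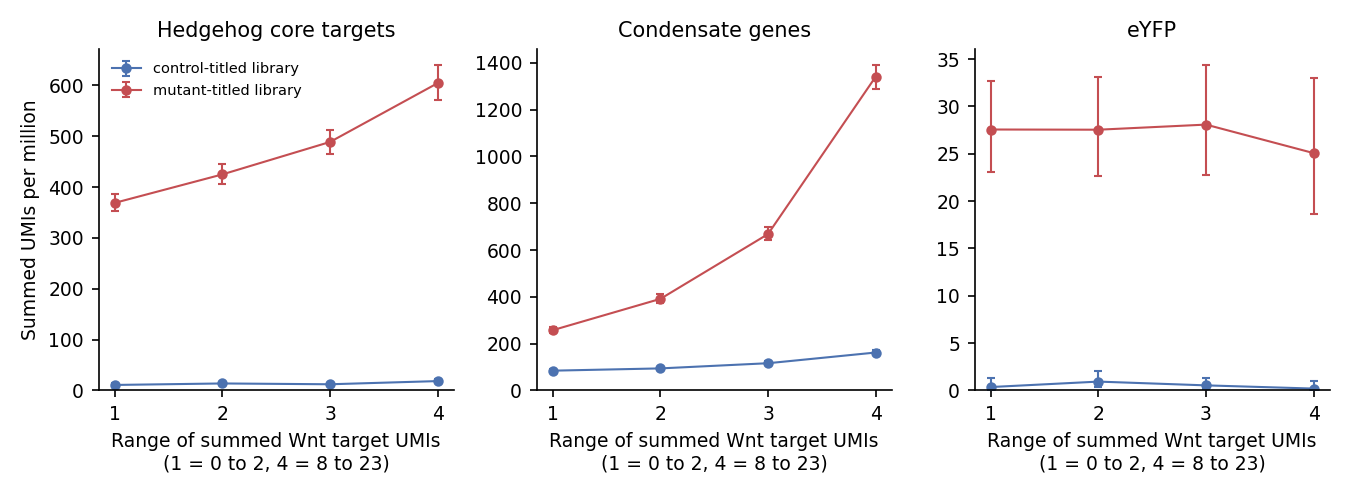
Summed CPM of the core Hedgehog targets, the condensate genes and eYFP in dermal cells (vertical axes) by range of the summed Wnt target UMIs (horizontal axes), with exact 95% Poisson intervals for each library. Condensate genes stood at 257 in the lowest and 1341 in the highest range of the mutant library, whereas eYFP stood between 25.1 and 28.1.

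Beyond these pathways, the highest ratios among dermal genes belonged to genes of varied function. Pdlim3, whose product belongs to the actin cytoskeleton, was 191-fold higher (111 to 360), and the hyaluronan link protein gene Hapln3 47.1-fold (36.4 to 61.9). Fxyd7, a regulator of the sodium pump, was at 128 against 11.9 CPM, 10.8-fold higher. The long non-coding transcript AA465934 was 46.1-fold higher (37.8 to 56.7) in dermal cells, and it was also higher in epidermal, muscle and macrophage cells.

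Genes that were lower in the mutant dermis included those of the calcium-binding protein Calb1, 18.4-fold lower (15.6 to 21.8) at 4.69 against 86.3 CPM, and neurogranin (Nrgn), 9.20-fold lower at 41.1 against 378 CPM. Enpp2, which encodes the secreted enzyme autotaxin, was 8.18-fold lower, and the zinc finger gene Casz1 7.67-fold lower. The secreted Wnt agonist Rspo1 was 6.54-fold lower (5.98 to 7.16), the BMP antagonist Grem1 4.78-fold lower (4.10 to 5.60) and the growth factor binding protein Igfbp5 4.15-fold lower (4.01 to 4.29). A pair of Iroquois transcription factors was lower, Irx3 6.17-fold and Irx5 3.42-fold. Srd5a2, Nrcam and Ctsh were 6.62, 5.01 and 4.30-fold lower.

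Contractile genes of smooth muscle were higher in the mutant dermis: all 3 measured members were higher, Tagln 5.98-fold, Acta2 3.84-fold and Myl9 2.49-fold, with a median log2 ratio of 1.93 (1.89 to 1.97). Of 22 collagen and matrix genes, 17 were within 1.5-fold, 3 were lower and 2 higher, at a median of -0.17. Elastin (Eln) was 2.23-fold lower, Vcan 1.70-fold and Fbln1 1.66-fold, while Col6a3 was 2.09-fold higher and Tnc 1.51-fold higher. Guidance and adhesion genes had no higher member among 14, with 4 lower and a median of -0.20. Ncam1 was 1.71-fold lower, Sema3a 1.57-fold and the chemokine gene Cxcl12 1.53-fold, and Itga8 was at 10.7 against 21.4 CPM. Over the 8 guidance members with at least 50 CPM the median was -0.07.

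Among growth factor pathways, FGF genes had 2 higher members of 11, Fgf10 (2.74-fold) and the feedback gene Spry1 (1.87-fold), with 9 within 1.5-fold and a median of 0.25. BMP pathway genes had a median of 0.14, with Fst, which encodes follistatin, 4.27-fold and Bmp2 2.41-fold higher, 1 lower member (Grem1) and 5 within 1.5-fold. Over the 3 BMP members with at least 50 CPM the median was -0.11. The 4 measured Notch genes were all within 1.5-fold, at a median of 0.00. Placode genes measured in dermal cells numbered 4, of which Bmp2, Lef1 and Pdgfa (2.11-fold) were higher, with a median of 1.10.

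Layer genes of the dermis showed no common direction. Of 7 upper dermis genes, Lef1 and Axin2 were higher, Crabp1, which encodes a retinoic acid binding protein, was 1.97-fold lower at 1204 against 2369 CPM, Apcdd1 was lower, and 3 were within 1.5-fold. Their median was -0.042, and 0.019 after thinning. Lower dermis and fascia genes had a median of 0.17 over 6 members, with Mfap5 1.66-fold higher, Cd34 1.74-fold lower and 4 within 1.5-fold. After thinning this median was 0.08. Adipogenic genes had a median of 0.50 over 4 members, with Ebf2 1.54-fold and Lpl 1.51-fold higher and 2 within 1.5-fold. Sox9, the only chondrogenic gene measured, had a log2 ratio of 0.12. Among epidermal genes in the dermal sums, 2 basal members had a median of 0.15 and 1 differentiation gene, Krt10, a log2 ratio of -0.20.

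In dermal cells, measures of dissection, handling and blood differed between the libraries beside these groups. Axial position genes in dermal cells had no higher member among 11, with 5 lower and 6 within 1.5-fold, at a median of -0.52 (-0.57 to -0.47). The lower members included En1 (2.52-fold lower), Hoxa9 (1.80-fold) and Hoxa7 (1.72-fold). Dissociation and stress genes had a median of 0.61 (0.52 to 0.67), with 6 of 11 higher, among them Ier2 (2.65-fold), Btg2 (2.27-fold) and Egr1 (1.95-fold), whereas Fos (1.03-fold) and Jun (1.06-fold) were within 1.5-fold. Hypoxia and glycolysis genes had a median of 0.39, with Hk2 1.99-fold higher, Pdk1 1.70-fold lower and 8 within 1.5-fold. All 6 measured hemoglobin genes were higher, Hbb-bs 6.14-fold at 1115 against 182 CPM, at a median of 2.46 (2.37 to 2.52). Not all classes shared these values. In epidermal cells the stress median was 0.009 (-0.072 to 0.23), with 2 of 7 higher and 1 lower. Hemoglobin medians were 0.25 in epidermal, 1.90 in muscle and -0.21 in macrophage cells. The 3 measured genes of the sex list (Xist and Y-linked genes) were within 1.5-fold, at a median of -0.03.

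Nearly all cell cycle genes were within 1.5-fold in the mutant dermis, while the share of cells with cycling UMIs and the inhibitor Cdkn1a were higher. The 37 S phase genes had a median of 0.17, with Rrm2 1.52-fold higher and the others within 1.5-fold. The 52 measured G2M genes had a median of 0.10, with Psrc1 1.98-fold and Gtse1 1.84-fold higher, and the median was 0.15 after thinning. Cell cycle inhibitors had a median of 0.28 over 5 members, with Cdkn1a and Btg2 higher, Cdkn1b 1.66-fold lower and 2 within 1.5-fold. Over the 4 inhibitors with at least 50 CPM the median was 0.72. At 3000 UMIs, 40.7% of mutant dermal cells (39.3 to 42.1) and 32.7% of control cells (31.7 to 33.7) had at least 3 UMIs of the 8 cycling genes, a difference of 7.98 points (6.25 to 9.71). It was 16.8 points at 5000 UMIs. That depth left out 1831 of 5130 mutant and 1721 of 8712 control dermal cells, against 348 and 287 at 3000 UMIs. The 2 depths therefore compare different cells, and the libraries lost unequal parts. In epidermal cells the shares were 53.2% and 51.1%, a difference of 2.07 points (-2.95 to 7.10), which was 6.35 points (1.45 to 11.3) at 5000 UMIs. In muscle cells they were 56.3% and 57.4%, a difference of -1.10 points (-6.00 to 3.79), which was -4.70 points (-9.47 to 0.03) at 5000 UMIs.

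In epidermal-like cells, genes of the early hair placode were low in the mutant library. Dkk4, a Wnt target and marker of placodes, had 379 UMIs in control and 1 UMI in mutant epidermal cells, 732-fold lower in CPM with an interval of 131 to 28996. Bmp2, a placode signal, was 32.5-fold lower (17.2 to 68.9), with 10 UMIs against 168. Lef1 was 4.52-fold lower (4.07 to 5.02), at 45.3 against 205 CPM. Sostdc1, a secreted inhibitor of Wnt and BMP signals, was instead 2.93-fold higher (2.71 to 3.17). These sums rest on 556 control cells with 5822065 UMIs and 1397 mutant cells with 11247810 UMIs, from clusters 9, 11 and 28.

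Of 9 measured placode genes, 6 were lower, 2 higher and 1 (Wnt10a) within 1.5-fold, at a median log2 ratio of -2.15 (-2.26 to -1.88), below all of the random lists. Ccn2 was 7.44-fold lower, Ltb 5.26-fold and the Wnt ligand gene Wnt10b 3.81-fold, and Pdgfa was 1.69-fold higher. The median was -1.32 with 10 CPM added, and the log2 ratio of Bmp2 was -3.22 with predicted doublets kept and -6.97 after thinning, against -5.02.

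**Figure D3:**
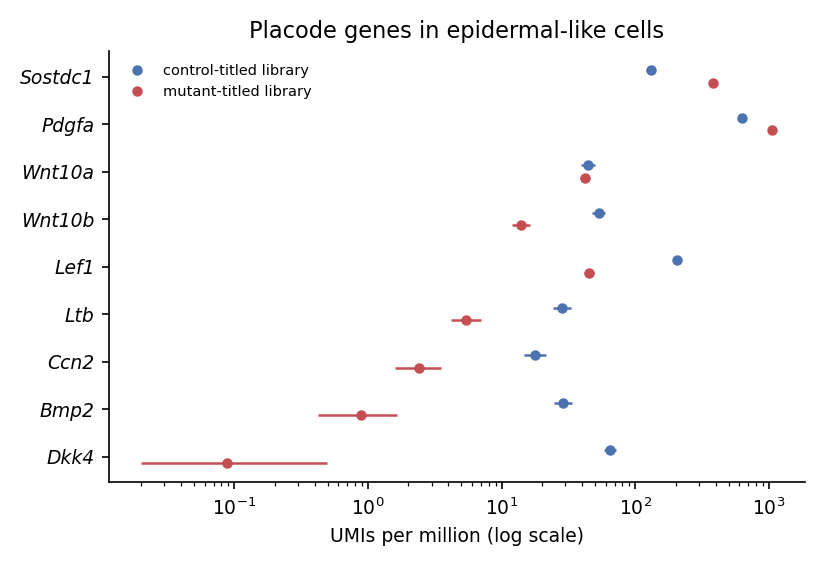
CPM (log scale) of each measured placode gene in epidermal cells, as points for each library with exact 95% Poisson intervals. Dkk4 stood at 65.1 in the control library and 0.0889 in the mutant library, and Sostdc1 was higher in the mutant library.

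Wnt targets were low in the mutant epidermis as well: 4 of 5 measured members were lower and Axin2, 1.35-fold lower, was within 1.5-fold, at a median of -1.22 (-1.48 to -0.88). Lef1, which is also in the placode list, was 4.52-fold lower, so the 2 lists are not separate. Znrf3 was 2.72-fold lower, Apcdd1 2.55-fold and Rnf43 1.86-fold. This median was -0.74 after thinning and -0.67 with 10 CPM added. None of the core Hedgehog targets reached 10 CPM in epidermal cells, so their list has no value there. Ptch1 was at 8.80 against 7.04 CPM, a ratio of 1.25 (0.860 to 1.85), Gli1 had 10 UMIs against 2, and eYFP 6 against 2. Cdkn1a was at 4.53 against 3.44 CPM, a ratio of 1.32 (0.773 to 2.34).

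Other genes with high ratios in the mutant epidermis were AA465934 (29.0-fold), the cystatin family gene Cstdc5 (22.3-fold), Kcne1l (9.97-fold), the homeobox gene Emx2 (9.47-fold), the imprinted gene Mest (5.76-fold) and the adhesion molecule gene Ntm (4.99-fold). Rtn1 (13.8-fold), the transcriptional repressor Ripply3 (10.4-fold), the adhesion molecule gene Nectin3 (9.76-fold) and Gadd45g (6.71-fold) were lower. With doublets kept, the log2 ratio was 1.39 against 2.53 for Mest, 2.42 against 3.24 for Emx2, 1.70 against 2.32 for Ntm and -1.89 against -2.75 for Gadd45g. After thinning it was 4.39 for Emx2. Basal epidermis genes had 2 higher members of 8, Col17a1 (2.50-fold) and Krt15 (1.72-fold), at a median of 0.36. Differentiation genes had Krt1 2.05-fold higher and Lor 1.61-fold lower among 4 members, at a median of 0.37. The median was 0.67 with doublets kept. Hypoxia and glycolysis genes had 7 higher members of 10 and a median of 0.73 (0.64 to 0.80), with Bnip3 6.11-fold and Vegfa 2.13-fold higher. Axial position genes had a median of -0.37 (-0.52 to -0.29), with Hoxc5 3.31-fold and Hoxc4 2.01-fold lower and 7 within 1.5-fold.

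Cell classes were present in different proportions. Dermal cells made up 75.6% (74.8 to 76.4) of kept control cells and 60.3% (59.3 to 61.4) of kept mutant cells, a difference of -15.3 points (-16.6 to -14.0). Epidermal cells made up 4.82% of control and 16.4% of mutant cells. Erythroid cells were at 0.460% and 2.65%, macrophages at 3.05% and 3.89%, and endothelial cells at 1.23% and 1.90%. Mast and other blood cells numbered 113 and 170. Glial cells were at 3.07% and 2.12%. Skeletal muscle cells, at 8.58% and 8.25%, mural cells, at 1.61% and 1.79%, and melanoblasts, at 0.607% and 0.564%, differed by amounts whose intervals included 0. Of cells neither dermal nor erythroid, muscle cells made up 35.8% of control and 22.3% of mutant cells, epidermal cells 20.1% and 44.3%, glial cells 12.8% and 5.71%, macrophages 12.7% and 10.5%, mural cells 6.70% and 4.82%, melanoblasts 2.54% and 1.52%, and endothelial cells 5.14% in both libraries. With this denominator macrophages and mural cells were lower rather than higher, the endothelial rise was gone, and the muscle shares (34.0 to 37.6 and 20.8 to 23.8) lay apart. Neuronal cells numbered 9 in the mutant library and 0 in the control library, which allows a share of up to 0.0260% at 3 counts. Dissection, dissociation and sorting can set such shares, and without replicate libraries their spread is unknown.

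**Figure D4:**
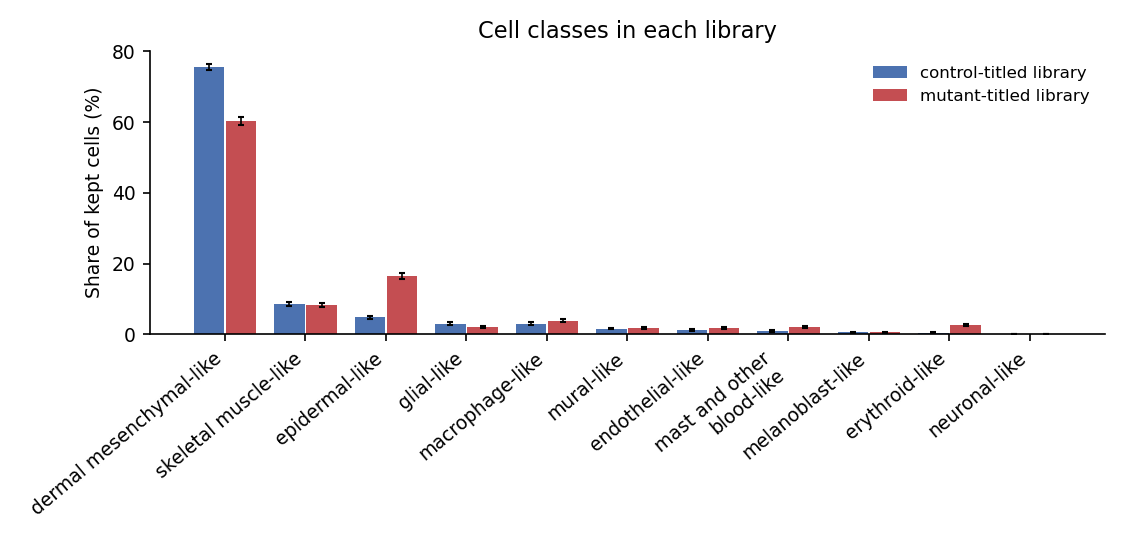
Share of kept cells (%, vertical axis) in each cell class (horizontal axis), as bars for each library with exact 95% Clopper-Pearson intervals. Dermal cells made up 75.6% of the control library and 60.3% of the mutant library.

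In skeletal muscle-like cells (989 control, 702 mutant), the alpha-actin gene Acta1 was 6.65-fold higher in the mutant library (125 against 18.8 CPM) and the troponin gene Tnnc1 5.07-fold higher. Both are leading genes of the small cluster 31, which held 6 control and 22 mutant cells. The follistatin gene Fst was 5.73-fold lower at 24.6 against 141 CPM, Gap43 3.78-fold lower and Igf1 3.25-fold lower. AA465934 was 49.0-fold higher. Axin2 was 1.30-fold higher (1.01 to 1.65), while the other Wnt targets measured were lower. Wnt targets had 4 lower members of 5 and a median of -0.88, with Wif1 4.44-fold and Nkd1 2.75-fold lower. This median was -0.56 after thinning. The reporter had 14 UMIs in mutant muscle cells (2.17 CPM) and 0 in control muscle cells (up to 0.204 CPM at 3 counts). It stood at 0.533 CPM in mutant epidermal cells, and at 4.70 CPM in mutant and 2.38 CPM in control macrophages. Lying between these levels, the source of the reporter in muscle cells was not settled. Ptch1 was 3.86-fold higher (2.56 to 5.89) at 10.2 CPM. It was at 8.80 against 7.04 CPM in epidermal cells and at 12.1 against 6.66 CPM in macrophages, mutant against control. Those classes held Ptch1 in the control library too, so their mutant levels do not measure free dermal RNA alone. Gli1 had 17 UMIs against 3 in muscle cells, 12.9-fold higher (3.74 to 68.9). Whether Ptch1 and Gli1 in muscle cells came from free dermal RNA was not settled. Stress genes had a median of 0.65, with Fos 2.51-fold and Junb 2.25-fold higher, and 0.36 with 10 CPM added.

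In macrophage-like cells (352 control, 331 mutant), AA465934 was 28.2-fold higher. The splicing factor gene Cwc22 was 3.56-fold higher and the lactate transporter gene Slc16a3 was at 55.4 against 17.8 CPM. Peg3 was 2.98-fold lower, Hpgd 2.40-fold lower, and Hmox1, which encodes heme oxygenase, 2.34-fold lower at 180 against 420 CPM. After thinning, the log2 ratio was 3.67 against 4.82 for AA465934 and 2.25 against 1.63 for Slc16a3. Hypoxia and glycolysis genes had a median of 0.49, and collagen and matrix genes a median of -0.72.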

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

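Of the values below, the look into erythroid cells was chosen only after the result was seen, and the tests on placode genes had their expected outcomes written before they were run. That the tests of axial level and of the basal and differentiating mix could not decide was seen only afterwards. The Wnt values by class and at a fixed class mix were added later.

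Several named genes stood out because dermal and epidermal cells moved in opposite directions between the libraries, 5 of the 42 looked at, and the difference between the classes was not tested, since each group has 1 library. Bmp2, a placode signal and BMP ligand, had a log2 ratio of 1.22 in dermal and -3.98 in epidermal cells, a difference of 5.20. Gadd45g, a stress-response gene, had 1.38 and -2.63, a difference of 4.02. Lef1, the Wnt effector, had 1.19 and -2.15, a difference of 3.34. The reverse held for Igfbp5, at -2.04 and 1.78 (difference -3.82), and for the adhesion molecule gene Ntm, at -0.72 and 2.22 (difference -2.94). These ratios were taken with 1 CPM added.

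Barcodes dominated by red cell RNA, nearly all of them left out by the gene minimum (2448 in the mutant and 376 in the control library), made up 20.7% of the mutant library (2460 barcodes, 19.9 to 21.4) and 2.83% of the control library (384 barcodes, 2.56 to 3.12). Erythroid cells that passed the filters in the mutant library held, outside hemoglobin, Ptch1 at 184 CPM (163 to 207) and Col1a1 at 589 CPM beside the red cell gene Alas2 at 538 CPM, and dermal cells held Ptch1 at 247 CPM by the same count.

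The low level of placode genes in the mutant epidermis was weighed against 3 explanations. Another mix of the large epidermal clusters is opposed by the medians within them, -2.03 in cluster 9 and -2.25 in cluster 11. Clusters 9 and 11 held 281 and 249 of 556 control and 704 and 625 of 1397 mutant epidermal cells. Whether these clusters part basal from differentiating cells was not shown, so another mix of such cells stays open. Skin from another axial level also stays open. In epidermal cells with a UMI of Hoxc4, Hoxc5, Hoxc6 or Hoxc8 the placode median was -2.16 (-2.28 to -1.91), but these were 85.3% of control and 65.5% of mutant epidermal cells, so the value nearly repeats that of all cells, and a UMI of any of the 4 genes does not match the libraries for position. In the 82 control and 482 mutant cells without such a UMI the median was -1.44 (-1.84 to -0.93). A secreted Wnt inhibitor from the mutant dermis, where Dkk1 was higher, stays open as well. Wnt targets summed over endothelial, glial, mural and melanoblast cells had a median of -0.50 (-0.65 to -0.28), but glial cells gave 38.0% of these UMIs in the control and 22.8% in the mutant library. At the class mix of the control library the median was -0.12 (-0.35 to 0.03), and within each of the 4 classes its interval included 0. Muscle cells, whose values had been seen before, had a Wnt target median of -0.88 (-1.23 to -0.70), with 4 of 5 lower. The remaining member, Axin2, was 1.30-fold higher there (1.01 to 1.65). Some cells of the 4 classes are also exposed to the allele, and a delay in development between the pools was not tested.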

How the results depend on the processing

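No paired analysis was possible because each group has 1 library. The alternatives with cells picked by a Lef1 UMI or by the lack of immediate early gene UMIs, totals without hemoglobin, and erythroid cells counted as dermal were chosen after seeing the data. Of 92 alternative values of the 9 leading results, 58 of the planned ones stayed within the counting interval, 16 moved beyond it and 1 reversed, and of the later ones 8 stayed and 9 moved. Dermal Gli1 (log2 ratio 3.54), Ptch1 (5.51), core Hedgehog targets, condensate genes and epidermal placode genes kept their direction in every alternative run. For the other 106 results, 768 of 843 values stayed, 71 moved and 4 reversed.

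Unless a reason is given below, the cause was not tested. In dermal cells with no UMI of the 8 G2M genes (3256 control, 1532 mutant) the Wnt median reversed, from -0.23 to 0.15, and Gli1 was 3.99, Ptch1 5.79 and the condensate median 2.03. In cells with a Lef1 UMI (1326 and 1045) the Wnt median was -0.041, Gli1 3.13, Ptch1 5.75 and the condensate median 2.68. In cells without immediate early gene UMIs (1666 and 624) these were -0.37 for Wnt, 3.29 for Gli1 and 1.22 for condensate genes, with core Hedgehog targets at 4.32. With members of at least 50 CPM only, which leaves fewer genes, the Wnt median was -0.14, condensate 2.85, core Hedgehog targets 5.03 and placode -1.86. The same floor reversed BMP genes in dermal cells (-0.11), condensate genes in epidermal cells (-0.60, 1 gene left) and guidance genes in muscle cells (0.022, 1 gene left). With 10 CPM added, which shrinks ratios of scarce genes by construction, condensate was 1.01, core Hedgehog targets 2.80 and placode -1.32. Thinning before summing gave Ptch1 5.33 and condensate 1.73, and reversed the upper dermis median to 0.019. The condensate share difference was 19.6 points with at least 2 genes and 13.9 at 5000 UMIs. The cycling share difference was 10.1 points with at least 2 UMIs and 16.8 at 5000 UMIs. At 5000 UMIs, 1831 of 5130 mutant and 1721 of 8712 control dermal cells were left out. The dermal share difference was -13.1 points with erythroid cells counted as dermal. Core Hedgehog targets in epidermal cells had no main value, as no member reached 10 CPM, and gave 1.57 (1 gene) only with doublets kept. Depth limits scarce genes such as Sox2 and Dkk4, whose intervals are wide.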

Other observations

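The tests of AA465934 by its ratio between classes and against free RNA were chosen only after the result was seen. So were the share of Cdkn1a by condensate genes and the values by class and by a Ptch1 UMI for p53 targets. The other tests had their expected outcomes written before they were run.

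Targets of p53, a regulator of growth arrest and cell death, were higher in the mutant dermis beside Cdkn1a. Of 17 measured genes in a list of 24 written without Cdkn1a, 12 were higher, 0 lower and 5 within 1.5-fold. Among the higher ones, Eda2r, Sesn2, Zmat3, Fas, Bbc3 and Pmaip1 reached 10 CPM in the mutant library only, so the floor favoured higher members. Eda2r, a TNF receptor family gene, was 13.8-fold higher, Sesn2 8.83-fold, Plk2 6.72-fold, Phlda3 4.12-fold, Zmat3 3.98-fold and Bax, which promotes apoptosis, 1.97-fold, while Mdm2, the negative regulator of p53, was 1.41-fold higher. The median log2 ratio in other classes was -0.05 in epidermal, 0.02 in muscle, 0.06 in glial, -0.08 in endothelial, 0.33 in macrophage and 0.40 in mural cells. Thinned mutant dermal cells with a Ptch1 UMI, against those without, had a median of 0.28 (0.23 to 0.40), with 3 of 18 higher. In control dermal cells split alike it was 0.22 (-0.07 to 0.50), with 4 of 13 higher.

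Of 6 measured FGF pathway genes in the mutant epidermis, Etv4 (3.90-fold) and Etv5 (1.60-fold) were higher, Dusp6 was 1.87-fold lower and 3 were within 1.5-fold, at a median log2 ratio of 0.44. Mycn was 3.18-fold and the Hedgehog co-receptor gene Gas1 2.10-fold higher there, Id2 was 2.33-fold higher, and the growth inhibitor gene Btg1 was 2.99-fold lower. Cells with only Xist among the sex-linked transcripts scored made up 44.1% of control and 43.3% of mutant cells, and cells with only Y-linked transcripts 33.6% and 29.3%, so both pools held embryos of both sexes.

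Cdkn1a was weighed as part of a wider p53 response, as a sign of handling and as a condensate gene. The median of the other p53 targets, 0.98 (0.94 to 1.01), reached the level written in advance, so a p53 response in the mutant dermis is a candidate explanation. That median includes the genes that reached the expression floor in the mutant library only. Dissociation stress marked by 6 immediate early genes is opposed by cells without their UMIs, in which Cdkn1a was 21.5-fold higher (17.0 to 27.6). These cells were dissociated alike and not matched for depth, so stress without these transcripts was not tested. The other p53 targets were not compared in these cells. Within the mutant dermis, a Cdkn1a UMI was found in 14.1% of cells with none, 22.3% with 1 and 52.4% with at least 2 of the other condensate genes, a ratio of 3.71 between the last and first, so condensate-like cells may contribute too. Toxicity of the recombinase was not tested: the title of the control library names SmoM2YFP alone, so if control embryos lacked Axin2CreER, its presence goes with the groups. The labels do not say whether they received tamoxifen, so its toxicity was not tested either.

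AA465934, a non-coding transcript on chromosome 11 at 83291699 to 83294632, was higher by a like ratio in dermal, epidermal, muscle and macrophage cells. A response of cells that carry the active allele is opposed by its level in mutant epidermal cells, 0.991 times that in dermal cells (0.915 to 1.07), and free dermal RNA is opposed by Ptch1, whose ratio was 0.0357 (0.0290 to 0.0435). A haplotype carried with the Axin2CreER allele, Axin2 being on the same chromosome at 108920349 to 108950783, may explain it but stays open, and it requires that control embryos lacked that allele, which their title leaves unnamed. Among 6 other genes that differed in 1 direction in all 4 classes, 16.7% (1 gene, interval 0.421 to 64.1) lay on chromosome 11, against 8.39% of 5627 background genes, which is too few to decide. Of these 6, Cwc22 and Rbm45 lie 1497391 bases apart on chromosome 2, which was seen only afterwards.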
